A study of Mus musculus with 18 samples.

How the data were processed

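The values are from RNA sequencing of 18 libraries of sorted spleen T cells, made from total RNA as NEBNext Ultra libraries with single reads of 50 nt. The deposited values are FPKM, one per gene symbol and library, as the submitters' processing notes name Trimmomatic 1, TopHat2 2.0.11, Cufflinks and the GRCm38 genome build. The unit was inferred from that tool and from the values, which are fractional and never negative, since the files' header lines do not name it. The annotation behind the gene symbols and the strand setting were not given in the sources used here. Read counts were not used here, so the depth per library is unknown, and no counting intervals, floors or count models could be computed.

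The libraries were grouped by genotype and population from their titles into 6 groups of 3. Of 26665 genes listed, the 12265 with an FPKM of 1 or more in at least 3 of the 18 libraries were tested. The values were transformed as log2(FPKM + 1), with a pseudocount of 1, and fitted with limma 3.58.1 in R 4.3.3, using one mean per group, all 18 libraries and a variance trend on mean expression. The fit had 12 residual degrees of freedom and a median of 4.06 prior degrees of freedom. All tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. There were 9 comparisons of 2 groups (CD28-deficient minus wild type in each of 3 populations, Nrp1+ minus Nrp1-negative Treg in each genotype, and each Treg subset minus Tconv in each genotype). A further 3 tests took the difference of CD28 effects between populations: Nrp1-negative minus Nrp1+ Treg, Nrp1+ Treg minus Tconv and Nrp1-negative Treg minus Tconv.

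Before the data were examined, 29 gene lists with 558 entries were fixed, along with the model, the filter and the rule for named genes. The files held 535 of the entries and not 23 others. The lists covered the Treg signature, effector Treg, resting and naive T cells, Th1, Th2, Th17 and Tfh genes, costimulatory and coinhibitory receptors, antigen receptor and CD28 signalling components, immediate early genes, NF-kB targets, targets of IL-2 and STAT5, the BCL2 family and death receptors, the cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, the type I interferon response, chemokine receptors and homing, heat shock and handling stress, cytosolic ribosomal proteins, mitochondrially encoded genes, and markers of B, plasma, myeloid, CD8 T, NK, erythroid and platelet, and NKT and gamma-delta T cells. Cd28, Foxp3 and Nrp1 were left out of all lists because the mutation or the sort sets them. The 25 lists with more than 1 tested gene were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a comparison. The estimated correlation ran from 0.205 (NK cell markers) to 0.824 (Treg signature), far above the preset 0.01, so the p-values with the preset correlation are too small. A pass with the preset correlation alone is therefore weak evidence that a list moved. Camera compares a list with the other genes, while fry asks whether the genes of a list move, on balance, one way. Counts within a list were also adjusted over the list alone.

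The named genes follow a fixed rule. It takes Cd28, Foxp3 and Nrp1 as checks, and among called genes without overlap between the groups the 10 with the largest change each way (5 each way for Treg against Tconv and for the differences of CD28 effects). It leaves out unnamed gene models, antigen receptor and immunoglobulin segments, and microRNA, snoRNA and pseudogene symbols. It adds at most 4 called members of each list by size of change, and, whatever their p, Ikzf2, Il2ra, Ctla4, Icos, Dapl1, Igfbp4, Mki67 and Bcl2. A few genes that the rule names are not used here. Positions are from GENCODE mouse release 21 on GRCm38, which may differ from the annotation behind the files, and 168 of the 172 named genes had 1 position in it. Agreement of CD28 effects was measured as correlations across genes and as the overlap of calls against the product of the counts divided by the genes tested.

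Replicate numbers were checked for pairing by the correlation of libraries of equal number after the group means were removed, taken as pairing where it was above 0.1 for all 3 numbers. They paired the libraries in 6 of 9 comparisons, all but CD28-deficient against wild type in either Treg subset and Nrp1-negative Treg against Tconv in wild type, and 17 of 18 libraries correlated best with a library of their own number. A block on the number was run as an alternative. The other alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, no variance trend, only the compared groups in the model, quantile normalization, and leaving out each library in turn. Quantile normalization for Treg against Tconv, and leaving out together the 3 libraries that stood apart, were added after the data were seen. The code was tested on simulated data with 100 genes shifted at each of 2 sizes: at log2 1 it recovered 52%, 50% and 64%, and at log2 2 97%, 90% and 95%, for the CD28 effect in Nrp1+ Treg, Nrp1-negative Treg and Tconv, with 14, 8 and 10 false calls. The shifted genes had a mean log2 value above 2, and the noise was normal and independent between genes and libraries. Pairing, mixed libraries and shifts of whole libraries were not simulated, so these rates check the code and do not carry over to the real calls.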

Results

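RNA was sequenced from 18 libraries of mouse spleen T cells, 3 for each of 6 groups made of 2 genotypes and 3 sorted populations. The genotypes were wild type and CD28-deficient, CD28 being the receptor that gives T cells their classical costimulatory signal. The populations were Nrp1+ regulatory T cells (Treg), which the study calls thymic, Nrp1-negative Treg, which it calls peripheral, and conventional T cells (Tconv). Foxp3 is the transcription factor that defines Treg, and Nrp1 (neuropilin 1) is the surface receptor used to part the Treg subsets. Each library held one expression value, in FPKM (fragments per kilobase, scaled to the mapped fragments), for each of 26665 genes. The FPKM of a library summed to between 514726 and 994139, and between 10703 and 11741 genes reached an FPKM of 1. Read counts were not used here, so the depth is unknown and no counting intervals are given. All group values below are the mean FPKM ± SD of n = 3 libraries, and all changes are differences of log2(FPKM + 1) ± SE from the limma model, which understate the fold of genes with low FPKM. Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between these samples only.

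The sort markers separated the populations. Foxp3 was 115 ± 20.2 in wild type Nrp1+ Treg, 89.6 ± 29.1 in wild type Nrp1-negative Treg and 0.224 ± 0.0538 in wild type Tconv. In CD28-deficient mice it was 98.0 ± 8.96 in Nrp1+ Treg and 93.1 ± 15.5 in Nrp1-negative Treg. Nrp1 was 69.5 ± 13.9 and 64.6 ± 8.61 in wild type and CD28-deficient Nrp1+ Treg, against 0.787 ± 0.181 and 0.647 ± 0.179 in Nrp1-negative Treg, and 4.35 ± 1.18 in wild type Tconv. Cd28 itself (GRCm38 chromosome 1, 60716800 to 60773359) was not lower in the libraries labelled CD28-deficient. It was 76.1 ± 4.68 against 60.0 ± 2.75 in Nrp1+ Treg (0.34 ± 0.31, adjusted p = 1). It was 76.0 ± 19.0 against 48.1 ± 14.8 in Nrp1-negative Treg (0.67 ± 0.31, adjusted p = 0.77) and 88.8 ± 25.8 against 61.3 ± 25.2 in Tconv (0.58 ± 0.31, adjusted p = 0.547). The value of the whole gene therefore does not check the genotype labels, and every direction below rests on those labels.

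Several libraries stood apart from the rest. CD28-deficient Tconv replicate 3 carried Treg transcripts, with Foxp3 at 21.1, Nrp1 at 12.8, Ikzf2 at 20.5, Il2ra at 24.0 and Ctla4 at 27.3. Replicates 1 and 2 of that group had Foxp3 at 0.067 and 0.205, Nrp1 at 0.627 and 0.841, and Ikzf2 at 0.277 and 0.521. Since the variance of a gene is taken from all libraries of a fit, replicate 3 widens the SE of such genes in every comparison. CD28-deficient Nrp1+ Treg replicate 3 carried Tconv transcripts, with Pdlim4 at 8.14 (0.126 and 0.0332 in replicates 1 and 2), Ggt5 at 4.62 (0.0731 and 0.076), Slc16a5 at 4.89 (0.369 and 0.472) and Dapl1 at 28.4 (3.73 and 6.74). Wild type Nrp1-negative Treg replicate 1 had the lowest median log2 value (2.85) and the fewest genes at 0 (6002). Wild type Tconv replicate 1 had the highest FPKM sum (994139) and the heat shock gene Hspa1a at 86.2, and its Spearman correlations with replicates 2 and 3 were 0.919 and 0.91, while those within the other groups lay between 0.931 and 0.97. The small RNA locus Mir5105 took 26.9%, 20.8% and 19.4% of the FPKM sum in CD28-deficient Tconv replicate 3, wild type Nrp1-negative Treg replicate 1 and wild type Tconv replicate 1, and as little as 2.98% in another library. The 3 libraries that stood apart, as left out together in some fits, are these with 26.9%, 20.8% and 19.4%, while CD28-deficient Nrp1+ Treg replicate 3 stayed in those fits. The median change of all tested genes from wild type to CD28-deficient was -0.05 in Nrp1+ Treg, 0.19 in Nrp1-negative Treg and -0.16 in Tconv, and quantile normalization brought these medians to 0, 0.02 and 0.

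**Figure D1:**
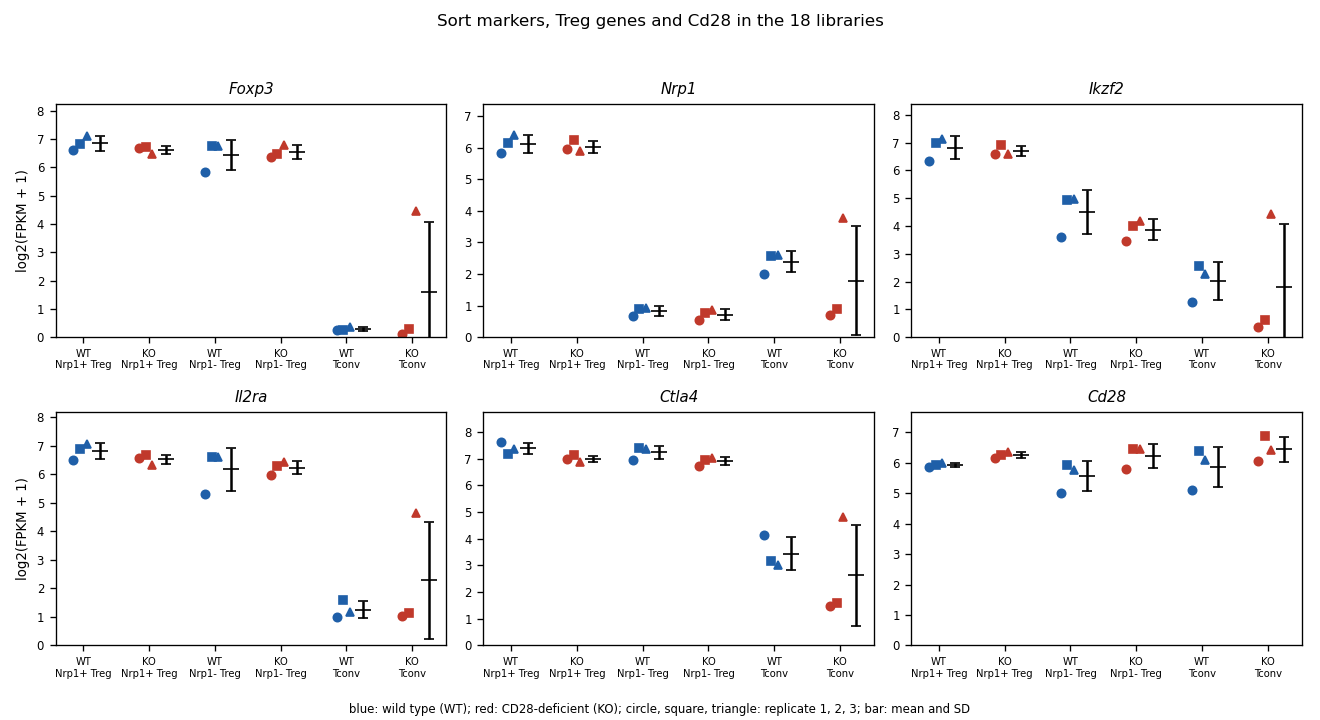
Foxp3, Nrp1, Ikzf2, Il2ra, Ctla4 and Cd28 in each of the 18 libraries, as log2(FPKM + 1) on linear axes, with points for libraries (blue wild type, red CD28-deficient; circle, square and triangle for replicates 1, 2 and 3) and bars for the mean and SD of 3 libraries, not drawn below 0. CD28-deficient Tconv replicate 3 lies above the other Tconv libraries for the Treg genes (Foxp3 FPKM 21.1 against 0.067 and 0.205), and Cd28 is not lower in CD28-deficient groups.

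In Nrp1+ Treg 21 of the 25 genes called for CD28 deficiency fell. Tox2, a transcription factor gene of follicular helper T cells (Tfh), fell by 1.77 ± 0.26 (3.22 ± 0.447 against 13.6 ± 3.29). Asb2, a ubiquitin ligase subunit (chromosome 12, 103321142 to 103356001), fell by 1.66 ± 0.26 (2.30 ± 0.695 against 9.29 ± 0.723), and Cebpa, a transcription factor of myeloid differentiation (chromosome 7, 35119293 to 35121928), fell by 1.65 ± 0.20 (1.20 ± 0.259 against 5.95 ± 1.12). The inhibitory receptor gene Lilrb4 fell by 1.58 ± 0.24 and its paralog Gp49a by 1.64 ± 0.18 (reads can be shared within this pair). Cd22, an inhibitory lectin known from B cells, fell by 1.04 ± 0.12, and the cytokine gene Lif by 0.88 ± 0.16. Actg2, a smooth muscle actin, fell by 1.83 ± 0.28, Ier5l by 1.69 ± 0.30, the amino acid transporter gene Slc7a10 by 1.20 ± 0.23, Sccpdh by 1.15 ± 0.17 and the gap junction gene Gjb2 by 1.06 ± 0.18. Higher were Scin, an actin-severing protein (1.08 ± 0.15, 2.58 ± 0.61 against 0.689 ± 0.185), the cell adhesion gene Dscam (1.04 ± 0.14, 2.99 ± 0.179 against 0.956 ± 0.315) and the immunoglobulin superfamily gene Igsf3 (0.82 ± 0.13, 2.14 ± 0.156 against 0.783 ± 0.0881).

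Among the lists for Nrp1+ Treg, all 24 effector Treg genes had a change below 0. Of these 0 passed over all genes and 11 were lower when adjusted over the list alone, with a median change of -0.66. Camera gave this list an adjusted p = 1.23e-17 with the preset correlation of 0.01, and an adjusted p = 0.139 with an estimated correlation (0.372). The cell cycle list had 0 of 29 called and 8 lower when adjusted over the list alone (median -0.31, adjusted p = 9.92e-15), with an adjusted p = 0.139 with an estimated correlation. In the Tfh list 1 of 16 fell, Tox2, and 6 were lower when adjusted over the list alone (median -0.48, adjusted p = 5.45e-11, and adjusted p = 0.139 with an estimated correlation). Lif was the call among 18 targets of IL-2 and STAT5 (3 lower when adjusted over the list alone, adjusted p = 3.15e-05, and adjusted p = 0.381 with an estimated correlation). Cd22 was the call among 6 B cell markers (2 lower when adjusted over the list alone, adjusted p = 0.00014, and adjusted p = 0.139 with an estimated correlation). None of the 22 Treg signature genes passed (median -0.30, adjusted p = 0.000404, and adjusted p = 0.65 with an estimated correlation). Resting and naive T cell genes had a median of 0.10 with 0 of 22 called (adjusted p = 3.58e-05, and adjusted p = 0.436 with an estimated correlation). Without CD28-deficient Nrp1+ Treg replicate 3 that list had a median of 0.02 and no longer passed with the preset correlation (adjusted p = 0.0639). The costimulatory receptor Icos was 33.7 ± 2.10 against 55.5 ± 3.13 (-0.70 ± 0.22, adjusted p = 0.565), and the proliferation marker Mki67 2.15 ± 0.0941 against 3.56 ± 0.159 (-0.54 ± 0.14, adjusted p = 0.324). Changes of Ctla4 (-0.40), Il2ra (-0.28), Ikzf2 (-0.12), Bcl2 (-0.10), Igfbp4 (-0.33) and Dapl1 (1.11) each had an adjusted p = 1. Dapl1 was at 0.35 ± 0.43 and Igfbp4 at -0.84 ± 0.28 without that replicate 3.

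Over 12265 tested genes limma called 25 in Nrp1+ Treg, 4 higher and 21 lower, and 469 had an unadjusted p under 0.05. In all 25 the libraries of the genotypes did not overlap. Chance gives this in 10% of unselected genes at 3 against 3, but a call for the same difference favours it. It is therefore no separate support, here or for the calls below. The fourth higher gene, the microRNA locus Mir1247, fell outside the naming rule and was chosen after its values were seen: it was listed at 0 in 15 libraries and at 39.5, 31.8 and 28.0 in CD28-deficient Nrp1+ Treg, so no fold is given. Whether this reflects how the values of that group were quantified was not tested. Of the 25 lists, 16 passed with the preset correlation, 0 with the estimated one and 0 in fry (lowest adjusted p = 0.0729). The count was 3 with a pseudocount of 0.1, 51 after quantile normalization and 130 without the 3 libraries that stood apart, which lie outside this comparison. It was 12 without CD28-deficient replicate 2, 14 without CD28-deficient replicate 3 and 12 without wild type replicate 3.

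In Nrp1-negative Treg 22 of the 25 genes called for CD28 deficiency fell. Ccl5, a chemokine of activated T cells, fell by 3.12 ± 0.45 (7.45 ± 2.63 against 73.8 ± 28.5). The anti-inflammatory cytokine gene Il10 (chromosome 1, 131019845 to 131024974) fell by 3.02 ± 0.30 (0.546 ± 0.387 against 12 ± 5.61). Tigit (chromosome 16, 43648867 to 43664146), an inhibitory receptor, fell by 2.99 ± 0.42 (3.28 ± 0.689 against 33.1 ± 4.97), Klrg1, a lectin receptor of terminally differentiated cells, by 2.46 ± 0.37 (0.262 ± 0.0872 against 5.92 ± 0.343), and Lag3, another inhibitory receptor, by 1.54 ± 0.28 (6.29 ± 0.577 against 20.4 ± 4.41). The protease inhibitor gene Serpina3f fell by 1.86 ± 0.15 and the long noncoding RNA Miat (chromosome 5, 112213228 to 112229395) by 1.61 ± 0.11 (0.464 ± 0.199 against 3.46 ± 0.287). Lilrb4 fell by 1.45 ± 0.24, Sccpdh by 1.37 ± 0.17, Asb2 by 1.37 ± 0.26, Lif by 0.86 ± 0.16 and Cd22 by 0.78 ± 0.12. The serine protease gene Prss12 rose by 1.02 ± 0.14 (2.22 ± 0.029 against 0.594 ± 0.241), Serpinb1a by 0.94 ± 0.17 (4.50 ± 0.22 against 1.88 ± 0.442) and Igsf3 by 0.68 ± 0.13 (1.07 ± 0.155 against 0.292 ± 0.0329).

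Of the effector Treg list, 3 of 24 genes fell (Il10, Klrg1 and Lag3) and 10 were lower when adjusted over the list alone. Its median was -0.56 and camera passed with both correlations (adjusted p = 4.44e-33, and adjusted p = 0.0106 with an estimated correlation), while fry did not pass (adjusted p = 0.119). Th1 genes, those of interferon-gamma producing helper cells, had 1 of 13 called, Ccl5, with 6 lower and 1 higher when adjusted over the list alone (median -0.75, adjusted p = 3.03e-20, and adjusted p = 0.00622 with an estimated correlation). Il10 was also the call among 6 Th2 genes, whose median was -0.07 and mean -0.52 (2 lower when adjusted over the list alone, adjusted p = 4.95e-06, and adjusted p = 0.0399 with an estimated correlation). The 6 B cell markers had Cd22 as their call (2 lower when adjusted over the list alone, adjusted p = 5.94e-10, and adjusted p = 0.0149 with an estimated correlation). In fry the Th1, Th2 and B cell lists had adjusted p = 0.111, 0.184 and 0.119. Without the 3 libraries that stood apart, the estimated-correlation p of the Th2 and B cell lists became 0.127 and 0.109. Tigit was the call among 22 Treg signature genes, also when adjusted over the list alone (adjusted p = 8.77e-16, and adjusted p = 0.149 with an estimated correlation). Tigit and Lag3 were the calls among 21 costimulatory and coinhibitory receptors, 2 also when adjusted over the list alone (median -0.03, adjusted p = 1.26e-07, and adjusted p = 0.221 with an estimated correlation). Il10 and Lif were those among 18 targets of IL-2 and STAT5 (3 lower when adjusted over the list alone, adjusted p = 5.64e-10, and adjusted p = 0.0797 with an estimated correlation). Resting and naive T cell genes had 0 of 22 called and a median of 0.38, with 2 higher when adjusted over the list alone (adjusted p = 0.00105, and adjusted p = 0.46 with an estimated correlation). Its median was 0.05 without the 3 libraries that stood apart. Icos (-0.48), Igfbp4 (-0.58), Mki67 (-0.20) and Ikzf2 (-0.64) each had an adjusted p = 0.77, and Ctla4 (-0.33), Bcl2 (0.14), Dapl1 (0.23) and Il2ra (0.06) had adjusted p = 0.811, 0.843, 0.848 and 0.968. Wild type replicate 1, which stood apart, was the lowest of the wild type libraries for each of these genes and pulls their changes upward. In wild type replicates 1, 2 and 3 Icos was 30.3, 63 and 56.3, against 31.5, 31.9 and 38.3 in CD28-deficient ones. Igfbp4 was 65.9, 148 and 136 against 75.9, 71.5 and 73.1, and Il2ra 38.3, 97 and 95.9 against 61.5, 77.6 and 85.1.

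limma called 25 genes in Nrp1-negative Treg, 3 higher and 22 lower, with 544 at an unadjusted p under 0.05, and in all 25 the libraries of the genotypes did not overlap, which the call itself favours. With the preset correlation 16 lists passed, with the estimated one 4 and in fry 0. Camera compares a list with the other genes, whose median was 0.19 here, and so gave a lower call to 3 lists with a median above 0: NF-kB targets (0.07), BCL2 family genes (0.06) and chemokine receptors (0.21). The count was 11 with a pseudocount of 0.1, 9 with only the compared groups in the model, 80 after quantile normalization (12 higher and 68 lower) and 120 without the 3 libraries that stood apart. Leaving out CD28-deficient replicates 1, 2 or 3 gave 16, 6 and 16, and leaving out wild type replicates 2 or 3 gave 7 and 16.

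In CD28-deficient Tconv all 97 called genes fell. Ccl5 (chromosome 11, 83525778 to 83530518) fell by 4.85 ± 0.45 (4.88 ± 2.33 against 198 ± 160, adjusted p = 2.5e-05). Cxcr3, the chemokine receptor of Th1 cells (chromosome X, 101731535 to 101734269), fell by 2.90 ± 0.35 (4.65 ± 4.24 against 35.0 ± 7.67). The cytotoxic granule genes Nkg7 and Gzmk fell by 3.01 ± 0.41 (4.31 ± 4.06 against 36.7 ± 15.8) and 2.52 ± 0.26 (0.081 ± 0.0785 against 5.72 ± 3.50), and Ifng, which encodes interferon-gamma, by 2.44 ± 0.50 (1.51 ± 1.08 against 14.5 ± 12.1). The calcium-binding protein genes S100a4 and S100a6 fell by 3.17 ± 0.40 (6.07 ± 2.98 against 64.9 ± 37.4) and 3.04 ± 0.38 (3.37 ± 1.53 against 36.5 ± 19.3). Lag3 fell by 2.42 ± 0.28 (1.24 ± 1.11 against 10.4 ± 3.36), the inflammatory caspase gene Casp1 by 2.36 ± 0.24 and the myosin gene Myo1f by 2.56 ± 0.24.

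By list, 8 of 13 Th1 genes fell in CD28-deficient Tconv and 12 were lower when adjusted over the list alone, with a median of -1.66. This list held with both correlations (adjusted p = 1.11e-29, and adjusted p = 0.00102 with an estimated correlation) and in fry (adjusted p = 8.99e-06). The 8 became 5 without wild type Tconv replicate 1. Of 16 Tfh genes 6 fell, among them the inhibitory receptor gene Pdcd1 (-1.93 ± 0.41), the follicle-homing receptor gene Cxcr5 (-1.93 ± 0.37), Tox2 (-1.89 ± 0.26) and Angptl2 (-2.10 ± 0.23). Without CD28-deficient Tconv replicate 3 Pdcd1 was at -2.58 ± 0.29 and Cxcr5 at -2.45 ± 0.31. In that list 11 were lower when adjusted over the list alone (median -0.80, adjusted p = 1.61e-19, and adjusted p = 0.0502 with an estimated correlation). The effector Treg list had 7 of 24 lower and 13 when adjusted over the list alone (median -0.80, adjusted p = 2.55e-13, and adjusted p = 0.114 with an estimated correlation). Chemokine and homing receptors had 6 of 23 lower, also 6 when adjusted over the list alone, among them Cxcr3, Cxcr6 (-1.19 ± 0.23) and the integrin gene Itgb1 (-1.70 ± 0.30; adjusted p = 2.34e-05, and adjusted p = 0.509 with an estimated correlation). Lag3 and Pdcd1 were the calls among 21 costimulatory and coinhibitory receptors (7 lower when adjusted over the list alone, adjusted p = 5.22e-06, and adjusted p = 0.509 with an estimated correlation). The NF-kB targets Bcl3 (-1.11 ± 0.21) and Icam1 (-1.08 ± 0.22) fell (2 of 20, 5 when adjusted over the list alone, adjusted p = 6.1e-05, and adjusted p = 0.509 with an estimated correlation). The survival genes Bcl2a1d (-1.49 ± 0.25) and Bcl2a1b (-1.32 ± 0.26), close paralogs, were the calls among 19 genes of the BCL2 family and death receptors (3 lower when adjusted over the list alone, adjusted p = 0.137). The granzyme genes Gzmb (-1.87 ± 0.31) and Gzma (-1.72 ± 0.22) were single calls in the IL-2 and STAT5 list (3 of 18 lower when adjusted over the list alone, adjusted p = 0.0977) and the NK cell list. That NK cell list had 3 of 5 lower when adjusted over the list alone (median -0.48, adjusted p = 0.00016, and adjusted p = 0.0912 with an estimated correlation). Cd22 fell by 1.63 ± 0.12 (0.300 ± 0.0642 against 3.04 ± 0.409), as 1 of 6 B cell markers.

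No gene passed in several other lists for Tconv. Type I interferon response genes had 0 of 24 called and 10 lower when adjusted over the list alone (median -0.50, adjusted p = 8.01e-07, and adjusted p = 0.509 with an estimated correlation). The Treg signature had 0 of 22 called and a median of -0.01 (adjusted p = 0.195), beside the Treg transcripts of CD28-deficient replicate 3. Without the 3 libraries that stood apart its median was -0.55 (adjusted p = 2.35e-12, and adjusted p = 0.148 with an estimated correlation). Resting and naive T cell genes had a median of -0.07 (adjusted p = 0.0911). Icos (-0.76 ± 0.22) had an adjusted p = 0.21, Mki67 (-0.62 ± 0.14) 0.0666, Igfbp4 (-0.81 ± 0.35) 0.48, Il2ra (1.02 ± 0.66) 0.604, Ctla4 (-0.81 ± 0.60) 0.658, Ikzf2 (-0.23 ± 0.75) 0.976, Bcl2 (-0.06 ± 0.31) 0.988 and Dapl1 (-0.09 ± 0.53) 0.992. Without CD28-deficient Tconv replicate 3 the change was -0.16 ± 0.33 for Il2ra, -1.91 ± 0.28 for Ctla4, -1.55 ± 0.42 for Ikzf2, -0.16 ± 0.35 for Bcl2 and 0.07 ± 0.61 for Dapl1. Ctla4, Mki67 (-0.70 ± 0.16) and Nrp1 (-1.60 ± 0.23, from -0.61 ± 0.53) passed without that library.

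In total 97 genes were called in Tconv, 0 higher and 97 lower, with 1185 at an unadjusted p under 0.05, and in all 97 the genotypes did not overlap, which the call itself favours. After quantile normalization 113 were called, 4 higher and 109 lower, of which 65 were among the 97. Of the lists 12 passed with the preset correlation, 1, Th1, with the estimated one and 9 in fry. With replicate number as a block, which the numbers allow because they pair the libraries here, the count was 154, and with only the compared groups in the model it was 3, 2 higher and 1 lower. Leaving out CD28-deficient replicates 1, 2 or 3 gave 46, 44 and 152, and leaving out wild type replicates 1 or 2 gave 50 and 55. Leaving out wild type Nrp1-negative Treg replicate 1, which lies outside this comparison, gave 258. Without all 3 libraries that stood apart it was 311.

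**Figure D2:**
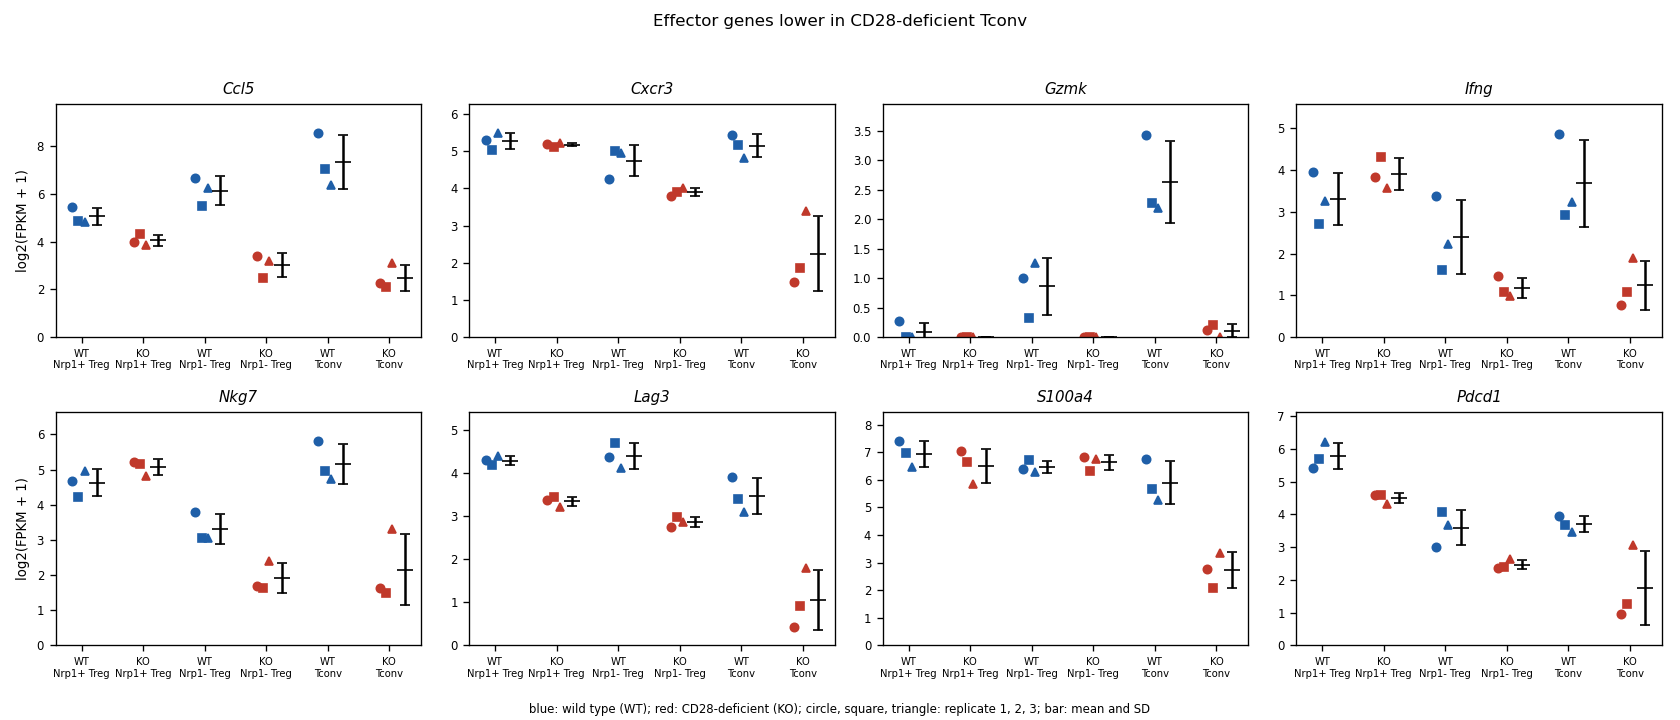
Ccl5, Cxcr3, Gzmk, Ifng, Nkg7, Lag3, S100a4 and Pdcd1 in each of the 18 libraries, as log2(FPKM + 1) on linear axes, with points for libraries (blue wild type, red CD28-deficient; circle, square and triangle for replicates 1, 2 and 3) and bars for the mean and SD of 3 libraries, not drawn below 0. The 3 CD28-deficient Tconv libraries lie below the 3 wild type Tconv libraries in each panel, for example at a mean Ccl5 of 4.88 against 198 FPKM.

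Some genes were called lower in both Treg subsets of CD28-deficient mice. Of 21 lower calls in Nrp1+ Treg and 22 in Nrp1-negative Treg, 12 were shared, where 0.038 would be expected from list sizes alone if the comparisons were independent. They are not fully so, since replicate numbers pair the libraries of the Treg subsets and each gene has 1 variance estimate for all comparisons, and the expected numbers of shared genes take no account of this. They were Apol9b, Asb2, Cd22, Cebpa, Gjb2, Gp49a, Lif, Lilrb4, Plekhg3, Sccpdh, Slc7a10 and Ttc39c, and Igsf3 was shared among the higher calls (0.00098 expected). Apol9b has a close paralog, Apol9a. With a pseudocount of 0.1 the 12 became 1, with no filter 6, with no variance trend 7, with replicate number as a block 16, all of the 12 among them, after quantile normalization 20, 10 of them among the 12, and without the 3 libraries that stood apart 54, 11 of them among the 12. Leaving out CD28-deficient Nrp1-negative Treg replicates 1, 2 or 3 gave 4, 1 and 6, and CD28-deficient Nrp1+ Treg replicates 1, 2 or 3 gave 5, 4 and 5. Leaving out wild type Nrp1-negative Treg replicates 2 or 3 gave 1 and 5, and wild type Nrp1+ Treg replicates 1 or 3 gave 6 and 4. The 12 also became 6 without CD28-deficient Tconv replicate 2 or wild type Tconv replicate 2 or 3, which lie outside both comparisons. All 21 lower calls of Nrp1+ Treg were also below 0 in Nrp1-negative Treg, and all 22 the other way round. Lower calls shared with Tconv were 5 for Nrp1+ Treg (Asb2, Cd22, Cebpa, Tox2 and Ttc39c) and 7 for Nrp1-negative Treg (Asb2, Baiap3, Ccl5, Cd22, Cebpa, Lag3 and Ttc39c), where 0.17 would be expected in each case. Ttc39c changed by -0.90 ± 0.17, -0.95 ± 0.17 and -1.45 ± 0.17 in the 3 populations in the order Nrp1+ Treg, Nrp1-negative Treg and Tconv, while Slc7a10 was at 0.03 ± 0.23 in Tconv (adjusted p = 0.996).

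Across all tested genes the CD28 effects correlated weakly by Pearson r and more strongly by rank. Pearson r was 0.21 between the Treg subsets, 0.20 between Nrp1+ Treg and Tconv and 0.14 between Nrp1-negative Treg and Tconv. Spearman's rho was 0.50, 0.50 and 0.34 for the same pairs. These are correlations across genes, which are not independent replicates, so no p is given, and while the effects compared share no library, replicate numbers pair libraries across populations. For the third pair, Pearson r was 0.05 without CD28-deficient Tconv replicate 2, 0.04 without CD28-deficient Nrp1-negative Treg replicate 2, 0.04 without wild type Tconv replicate 1 and 0.07 without wild type Nrp1-negative Treg replicate 1. For the second it was 0.07 without wild type Tconv replicate 1, and for the first 0.11 without wild type Nrp1+ Treg replicate 1.

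**Figure D3:**
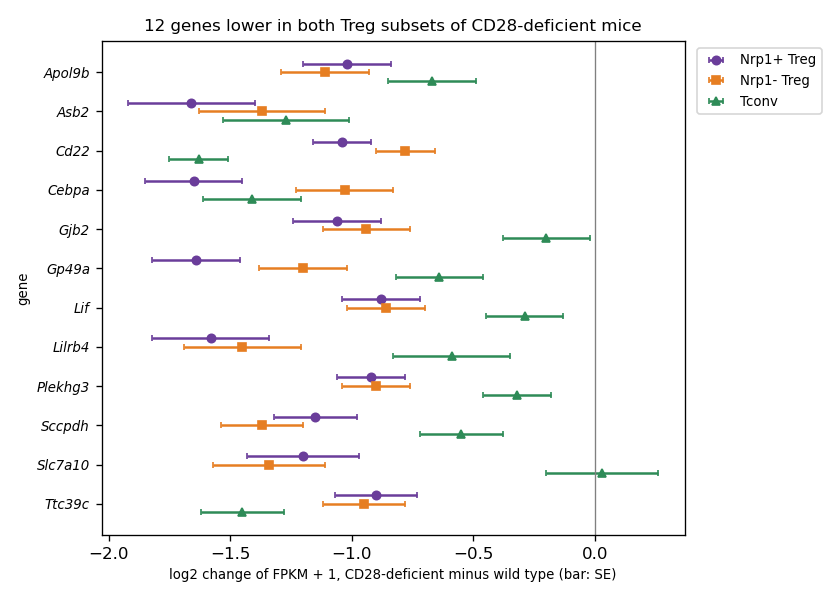
Change of log2(FPKM + 1) from wild type to CD28-deficient for the 12 genes lower in both Treg subsets (one gene per line), with points for the change in Nrp1+ Treg, Nrp1-negative Treg and Tconv and bars for the SE. Changes in Nrp1+ Treg run from -0.88 to -1.66 and in Nrp1-negative Treg from -0.78 to -1.45, and 4 of the 12 were also called in Tconv.

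The CD28 effect differed between populations for a small number of genes. Serpina3f (-1.68 ± 0.22, adjusted p = 0.0033) and Miat (-1.54 ± 0.16, adjusted p = 0.000195) had a more negative change in Nrp1-negative than in Nrp1+ Treg. The change was more negative in Tconv than in Nrp1+ Treg for Ccl5 (difference 3.85 ± 0.64), Nkg7 (3.46 ± 0.59), Cxcr3 (2.80 ± 0.50), Gzmk (2.43 ± 0.37) and Myo1f (2.33 ± 0.33), and for the Tfh genes Sostdc1 (1.36 ± 0.21) and Il21 (1.27 ± 0.19). Against Nrp1-negative Treg it was more negative in Tconv for S100a4 (3.34 ± 0.56), S100a6 (3.13 ± 0.54), Myo1f (2.51 ± 0.33), Smtn (1.65 ± 0.21), Sostdc1 (1.56 ± 0.21) and Il21 (1.23 ± 0.19), and less negative for Miat (-1.44 ± 0.16) and Serpina3f (-1.35 ± 0.22). Several of these lay near 0 in wild type cells of the other population, where log2(FPKM + 1) can hardly fall. Wild type Nrp1+ Treg had Gzmk at 0.201 or less, Miat at 0.142 or less, Sostdc1 at 0.655 or less and Il21 at 0.268 or less. In wild type Nrp1-negative Treg Smtn was 0.246 or less, Sostdc1 0.292 or less and Il21 0.196 or less. In wild type Tconv Miat was 0.165 or less and Serpina3f 0.795 or less. For these, in the tests with those populations, a floor cannot be told apart from a differing CD28 effect. The Th1 list differed between Nrp1+ Treg and Tconv, with 5 of 13 genes called and 11 when adjusted over the list alone (median 1.42, adjusted p = 9.19e-40, and adjusted p = 0.000243 with an estimated correlation). Its fry adjusted p was 0.000687. Camera also passed between the Treg subsets, with 0 called and 2 lower when adjusted over the list alone (median -0.52, adjusted p = 7.79e-22, and adjusted p = 0.00419 with an estimated correlation), but it did not pass in fry (adjusted p = 0.833). Between Nrp1-negative Treg and Tconv 0 were called and 8 when adjusted over the list alone (median 1.36, adjusted p = 6.32e-07, adjusted p = 0.307 with an estimated correlation and 0.0233 in fry). The differences in Ikzf2, Il2ra, Ctla4, Icos, Dapl1, Igfbp4, Mki67, Bcl2 and Cd28 passed in none of the 3 tests.

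limma called 3 genes for Nrp1-negative against Nrp1+ Treg, all lower, the third being Mir1247, which was listed at 0 in 15 libraries and whose quantification was not tested. It called 15 for Nrp1+ Treg against Tconv, all higher, and 9 for Nrp1-negative Treg against Tconv, 7 higher and 2 lower. At an unadjusted p under 0.05 there were 180, 267 and 1073 genes, and the medians of all tested genes were 0.24, 0.12 and 0.36. In each of the 3 tests 10 lists passed with the preset correlation, and 1, 1 and 0 with the estimated one, and 0, 1 and 1 in fry. The lists passing with the preset correlation fell to 6 between the Treg subsets without CD28-deficient Nrp1-negative Treg replicate 2. They fell to 6 between Nrp1-negative Treg and Tconv without wild type Tconv replicate 3 or wild type Nrp1-negative Treg replicate 1. The 15 became 6, 5 and 36 without CD28-deficient Tconv replicates 1, 2 and 3. It became 3, 4 and 8 without CD28-deficient Nrp1+ Treg replicates 1, 2 and 3, 6 without wild type Tconv replicate 2 and 4 without wild type Nrp1+ Treg replicate 2. The 9 became 5 and 25 without CD28-deficient Tconv replicates 2 and 3. It became 5 without CD28-deficient Nrp1-negative Treg replicate 1, 2 or 3, 5 without wild type Tconv replicate 1, and 4 without wild type Nrp1-negative Treg replicate 2 or 3.

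Nrp1+ and Nrp1-negative Treg differed in many genes beyond the sort marker Nrp1 (5.29 ± 0.53 in wild type). In wild type mice the integrin gene Itgb1 was higher in Nrp1+ Treg by 3.55 ± 0.30 (113 ± 5.23 against 9.10 ± 3.04), the enkephalin precursor gene Penk by 2.96 ± 0.55 (49.0 ± 9.73 against 5.53 ± 1.89), the chemokine receptor gene Ccr8 by 2.91 ± 0.33 and the IL-33 receptor gene Il1rl1 by 2.87 ± 0.21 (10.2 ± 1.61 against 0.526 ± 0.0601). Actg2 (2.52 ± 0.28), Npas4 (2.45 ± 0.33), Cd83 (2.39 ± 0.51), Ptpn5 (2.36 ± 0.23) and Rgs9 (2.35 ± 0.33) were also higher. Lower were Slc16a5 (-2.25 ± 0.40), the protease gene Mmp9 (-2.25 ± 0.18), Dapl1 (-2.18 ± 0.53), Pde3b (-2.09 ± 0.51), Miat (-2.04 ± 0.11), Gbp1 (-1.98 ± 0.29), Klrb1f (-1.73 ± 0.20) and Cited4 (-1.69 ± 0.19). Mki67 was higher (0.76 ± 0.14) and Igfbp4, a gene of naive T cells, lower (-1.56 ± 0.35). Ikzf2, which encodes Helios, was 116 ± 32.1 against 23.8 ± 11 without passing (2.32 ± 0.75, adjusted p = 0.108). Its libraries did not overlap (79.8, 126 and 141 against 11.1, 29.6 and 30.7). The variance of a gene is taken from all 18 libraries, so CD28-deficient Tconv replicate 3, outside this comparison, widens this SE. In CD28-deficient against wild type Tconv the SE of Ikzf2 was 0.42 without that library.

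In CD28-deficient mice the same contrast was led by Penk (4.56 ± 0.55, 38.7 ± 5.75 against 0.676 ± 0.202), Itgb1 (3.58 ± 0.30), Nkg7 (3.16 ± 0.41, 32.9 ± 4.92 against 2.87 ± 1.22), Bhlhe40 (3.04 ± 0.57), Rgs16 (2.99 ± 0.57), Klrg1 (2.95 ± 0.37), Tigit (2.91 ± 0.42), Il1rl1 (2.88 ± 0.21) and Ikzf2 (2.84 ± 0.75, adjusted p = 0.0427). Lower were Cited4 (-2.14 ± 0.19), Slc16a5 (-2.07 ± 0.40), Ly6c1 (-2.07 ± 0.25), Klrb1f (-1.82 ± 0.20), Rnase4 (-1.76 ± 0.24), Tubb2a (-1.74 ± 0.22), Als2cl (-1.68 ± 0.31), Serpinb1a (-1.66 ± 0.17) and Myo6 (-1.62 ± 0.25). CD28-deficient Nrp1+ Treg replicate 3, with its Tconv transcripts, is among the libraries compared. Without it the changes of Slc16a5 and Als2cl were -2.75 ± 0.25 and -2.07 ± 0.29. Igfbp4 was at -1.82 ± 0.28 (from -1.31) and Dapl1 at -2.06 ± 0.43 (from -1.30), and Dapl1 passed without it. Ikzf2 no longer passed when any 1 of the 6 libraries compared was left out, that one included (2.89 ± 0.87). Its libraries lay well apart, at 96.5, 120 and 96.1 against 9.97, 15 and 16.9. The SE takes in the spread of CD28-deficient Tconv replicate 3, outside this comparison. Without that library the SE of Ikzf2 was 0.42 in CD28-deficient against wild type Tconv. Whether these genes differed between genotypes in this contrast is the test between CD28 effects of the Treg subsets above.

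In each genotype 21 of the 22 Treg signature genes had a change above 0 in Nrp1+ against Nrp1-negative Treg. As a list they passed in fry in wild type (adjusted p = 0.0377) but not in CD28-deficient mice (adjusted p = 0.0522). In wild type 8 of 22 genes were higher (12 when adjusted over the list alone, adjusted p = 2.23e-08, and adjusted p = 0.472 with an estimated correlation). In CD28-deficient mice it was 10 of 22 (11 when adjusted over the list alone, adjusted p = 7.13e-15, and adjusted p = 0.392 with an estimated correlation). Examples in wild type were Itgb8 (2.14 ± 0.32), Swap70 (2.13 ± 0.29), Ikzf4 (2.0 ± 0.51) and Tnfrsf9 (1.82 ± 0.36). Of 24 effector Treg genes 10 were higher and 1, Il10 (-1.18 ± 0.30), lower in wild type (14 and 2 when adjusted over the list alone, adjusted p = 5.72e-05, and adjusted p = 0.472 with an estimated correlation). In CD28-deficient mice 8 were higher (13 when adjusted over the list alone, adjusted p = 1.07e-10, and adjusted p = 0.392 with an estimated correlation). Of the resting and naive genes 4 of 22 and 6 of 22 were lower (8 and 9 when adjusted over the list alone, with 2 and 0 higher, adjusted p = 1.33e-08 and 6.49e-06, and adjusted p = 0.472 and 0.412 with an estimated correlation). That list did not pass in fry (adjusted p = 0.339 and 0.104). The 6 became 8, and the median -0.59 from -0.51, without CD28-deficient Nrp1+ Treg replicate 3. Of 7 Th17 genes 2 and 3 were lower (3 and 4 when adjusted over the list alone, with 2 and 1 higher, adjusted p = 0.00337 and 0.0159, and adjusted p = 0.472 and 0.412 with an estimated correlation). In wild type 8 of 29 cell cycle genes were higher, such as Tk1 (1.21 ± 0.31) and Top2a (0.79 ± 0.17), and 10 when adjusted over the list alone (adjusted p = 0.000218, and adjusted p = 0.472 with an estimated correlation). In CD28-deficient mice 1 of them was higher, Tk1 (1.15 ± 0.31), also 1 when adjusted over the list alone, and 24 of the 29 were above 0 (adjusted p = 0.000878, and adjusted p = 0.451 with an estimated correlation). There Tk1 no longer passed when any 1 of the 6 libraries compared was left out, such as CD28-deficient Nrp1+ Treg replicate 3 (1.22 ± 0.35). Among 19 genes of the BCL2 family and death receptors 5 were higher in each genotype, and 6 in each when adjusted over the list alone. The adjusted p of that list was 0.0155 and 0.0136, and adjusted p = 0.472 and 0.451 with an estimated correlation.

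The subsets differed in 605 genes in wild type, 545 higher in Nrp1+ Treg and 60 lower, and in 500 in CD28-deficient mice, 384 higher and 116 lower. Quantile normalization evened the directions to 652 and 421 (60.8% higher, against 90.1%) and to 646 and 493 (56.7%, against 76.8%); the median of all genes was 0.19 and -0.03 before it. In 604 of the 605 and all 500 the groups did not overlap, which the call itself favours. In each genotype 14 lists passed with the preset correlation and 0 with the estimated one, and 8 and 3 in fry. Blocked by replicate number, which pairs these libraries, the counts were 1224 and 801. Under that block the Th17 (0.0831, CD28-deficient), BCL2 family (0.0653 and 0.0584) and glycolysis (0.181, wild type, from 0.0384) lists no longer passed while the myeloid list (0.0413, wild type, from 0.055) did. The wild type count was 348 without Nrp1+ Treg replicate 3. The CD28-deficient count was 328 without Nrp1-negative Treg replicate 1, 329 and 322 without Nrp1+ Treg replicates 1 and 2, and 831 without wild type Nrp1-negative Treg replicate 1. Without the 3 libraries that stood apart the counts were 913 (556 higher and 357 lower) and 1853 (706 and 1147), the latter with more genes lower than higher. With only the compared groups in the model the CD28-deficient directions were 603 and 609.

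Each Treg subset was compared with Tconv. Wild type Nrp1+ Treg were higher in Foxp3 (6.56 ± 0.74, by the sort), Lrrc32, the receptor for latent TGF-beta (6.23 ± 0.74, 77.9 ± 16.2 against 0.0403 ± 0.052), Il2ra, the IL-2 receptor alpha chain (5.55 ± 0.66), Ikzf2 (4.80 ± 0.75) and the relaxin gene Rln3 (4.52 ± 0.67). Lower were Pdlim4 (-5.48 ± 0.57, 0.0815 ± 0.0159 against 48.7 ± 16.2), Dapl1 (-4.26 ± 0.53), Pde3b (-4.17 ± 0.51), Slc16a5 (-4.14 ± 0.40) and Ggt5 (-4.13 ± 0.42). CD28-deficient Nrp1+ Treg were higher in Ikzf2 (4.91 ± 0.75), Lrrc32 (4.63 ± 0.74), the inhibitory receptor gene Ctla4 (4.36 ± 0.60) and Il2ra (4.25 ± 0.66), and lower in Pdlim4 (-4.38 ± 0.57), Pde3b (-3.50 ± 0.51), Slc16a5 (-3.30 ± 0.40), Ggt5 (-3.21 ± 0.42) and Dapl1 (-3.06 ± 0.53). CD28-deficient Tconv replicate 3, with its Treg transcripts, and Nrp1+ Treg replicate 3, with its Tconv transcripts, are among the libraries compared. Without the former the changes of Ikzf2, Lrrc32, Ctla4 and Il2ra were 6.23 ± 0.42, 6.03 ± 0.28, 5.45 ± 0.28 and 5.43 ± 0.33. Without the latter those of Pdlim4, Pde3b, Slc16a5, Ggt5 and Dapl1 were -5.40 ± 0.29, -4.32 ± 0.36, -3.99 ± 0.25, -4.01 ± 0.17 and -3.82 ± 0.43.

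Nrp1-negative Treg of wild type mice were higher in Il2ra (4.92 ± 0.66), Lrrc32 (4.84 ± 0.74), Coro2a (4.0 ± 0.58) and Ctla4 (3.80 ± 0.60), and lower in Pdlim4 (-5.00 ± 0.57), the NK receptor gene Klrd1 (-3.39 ± 0.39), Ggt5 (-3.31 ± 0.42), Nme4 (-2.72 ± 0.24) and Atp8b4 (-2.65 ± 0.38). Those of CD28-deficient mice were higher in Ctla4 (4.28 ± 0.60), Il2ra (3.95 ± 0.66) and Coro2a (3.95 ± 0.58), and lower in Pdlim4 (-4.46 ± 0.57), Klrd1 (-3.57 ± 0.39), Ggt5 (-3.09 ± 0.42), Atp8b4 (-2.72 ± 0.38) and App (-2.24 ± 0.20). Without CD28-deficient Tconv replicate 3 the changes of Ctla4, Il2ra and Coro2a were 5.38 ± 0.28, 5.14 ± 0.33 and 5.0 ± 0.30. Icos was higher than in Tconv in all 4 contrasts, by 1.19 ± 0.22 and 1.25 ± 0.22 in wild type and CD28-deficient Nrp1+ Treg and by 0.97 ± 0.22 and 1.25 ± 0.22 in Nrp1-negative Treg.

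All 22 Treg signature genes were higher in Nrp1+ Treg than in Tconv in both genotypes, also when adjusted over the list alone (adjusted p = 2.38e-31 and 4.14e-28, and adjusted p = 0.0802 and 0.0739 with an estimated correlation). In Nrp1-negative Treg 17 and 15 of them were higher, 21 and 19 when adjusted over the list alone (adjusted p = 7.13e-44 and 3.25e-16, and adjusted p = 0.0279 and 0.24 with an estimated correlation). Effector Treg genes were higher too, 18 and 22 of 24 in Nrp1+ Treg and 11 and 12 in Nrp1-negative Treg (20, 23, 14 and 13 when adjusted over the list alone), with an adjusted p = 0.0802, 0.0714, 0.0353 and 0.175 with an estimated correlation. Th17 genes were higher in Nrp1-negative Treg, 4 of 7 in wild type and 5 of 7 in CD28-deficient mice (4 and 6 when adjusted over the list alone, adjusted p = 3.23e-11 and 3.03e-11, and adjusted p = 0.0241 and 0.0349 with an estimated correlation). An example was Ccr6 (1.93 ± 0.45 and 2.74 ± 0.45). In Nrp1+ Treg 3 of 7 in wild type and 6 of 7 in CD28-deficient mice were higher too. There the list had an adjusted p = 0.36 and 0.0999 with an estimated correlation. Targets of IL-2 and STAT5 in wild type Nrp1-negative Treg had 6 of 18 higher and 1 lower, with 11 and 1 when adjusted over the list alone (adjusted p = 2.98e-14, and adjusted p = 0.0372 with an estimated correlation). In Nrp1+ Treg 9 of 18 were higher and 1 lower in each genotype, and in CD28-deficient Nrp1-negative Treg 8 were higher. With an estimated correlation the list had an adjusted p = 0.221 and 0.2 in wild type and CD28-deficient Nrp1+ Treg, and 0.272 in CD28-deficient Nrp1-negative Treg. Resting and naive genes were lower, 14 and 12 of 22 in Nrp1+ Treg, where 1 was higher in wild type, and 10 and 3 in Nrp1-negative Treg (15, 13, 14 and 6 lower and 1, 1, 0 and 0 higher when adjusted over the list alone), with an adjusted p = 0.177, 0.0999, 0.288 and 0.298 with an estimated correlation. NK cell markers were lower in Treg, 4 and 2 of 5 in Nrp1+ and 4 and 3 in Nrp1-negative Treg (4, 2, 5 and 3 when adjusted over the list alone), with an adjusted p = 0.0768, 0.0739, 0.0241 and 0.0349 with an estimated correlation.

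Nrp1+ Treg and Tconv differed in 1545 genes in wild type (1022 higher, 523 lower) and 1484 in CD28-deficient mice (1181 and 303). Nrp1-negative Treg and Tconv differed in 551 (252 and 299) and 718 (589 and 129). After quantile normalization the directions were 1426 and 1672 (46% higher, against 66.1%), 1399 and 1416 (49.7%, against 79.6%), 646 and 613 (51.3%, against 45.7%) and 729 and 530 (57.9%, against 82%), the medians before it being -0.02, 0.09, -0.21 and 0.14. The groups did not overlap in 1530, 1484, 547 and 716 of the called genes, which the call itself favours. Lists passing numbered 13, 15, 13 and 14 with the preset correlation and 0, 0, 5 and 2 with the estimated one, and 12, 14, 7 and 13 in fry. With replicate number as a block the Th17 and NK cell lists of CD28-deficient Nrp1-negative Treg no longer passed with the estimated correlation (0.0989 each, from 0.0349). Blocked counts were 2144, 2038 and 1150 for the 3 contrasts whose numbers pair the libraries, the exception being Nrp1-negative Treg in wild type. Under the block the B cell list of CD28-deficient Nrp1+ Treg (0.0535, from 0.0235) and the ribosomal list of CD28-deficient Nrp1-negative Treg (0.0627, from 0.0295) no longer passed, while the myeloid list of the latter did (0.0498, from 0.0619). The 1545 became 2356 without wild type Nrp1-negative Treg replicate 1, and the 551 became 365 without wild type Tconv replicate 3. The 551 had more genes lower than higher, but 295 were higher and 282 lower without CD28-deficient Tconv replicate 3, and 507 and 232 without wild type Nrp1-negative Treg replicate 1. The 718 became 391 and 427 without CD28-deficient Tconv replicates 1 and 2, 429 without CD28-deficient Nrp1-negative Treg replicate 3 and 1392 without wild type Nrp1-negative Treg replicate 1. Without the 3 libraries that stood apart the 4 counts were 2355, 2459, 1012 (761 higher and 251 lower) and 2082.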

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

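The tests of the differences were planned, and the splits of the samples in this part were chosen after the results were seen. What drew attention here was the test of the difference between the CD28 effects of populations, at an adjusted p under 0.05. The effect differed between Nrp1-negative and Nrp1+ Treg in 3 genes: Serpina3f (-1.68), Miat (-1.54) and Mir1247, which was listed at 0 in 15 libraries and whose quantification was not tested. Between Nrp1+ Treg and Tconv it differed in 15 genes, led by Ccl5 (3.85), Nkg7 (3.46), Cxcr3 (2.80), Gzmk (2.43) and Myo1f (2.33). Between Nrp1-negative Treg and Tconv it differed in 9 genes. Among these were S100a4 (3.34), S100a6 (3.13), Myo1f (2.51), Smtn (1.65), Sostdc1 (1.56), Miat (-1.44) and Serpina3f (-1.35). Gzmk, Smtn, Sostdc1 and Miat lay near 0 in wild type cells of the population with the smaller change, and Serpina3f was 0.795 or less in wild type Tconv. For the former, and for Serpina3f in the test with Tconv, a floor cannot be told apart from a differing CD28 effect. Without CD28-deficient Tconv replicate 3 the 15 became 36 and the 9 became 25. At the lowest the 15 became 3 without CD28-deficient Nrp1+ Treg replicate 1, and the 9 became 4 without wild type Nrp1-negative Treg replicate 2 or 3.

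Of 100 splits of the libraries drawn for each test, 10, 9 and 10 gave as many genes as the real 3, 15 and 9, the real split included. Of the 9, 8 and 9 other such splits, 8, 8 and 9 exchanged unequal numbers of libraries in the populations compared, as did the highest ones, which called 24, 30 and 61 genes. An unequal exchange turns CD28 effects that the populations share into differences between them, so these splits do not measure what chance gives for these counts.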

How the results depend on the processing

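Leaving out together the 3 libraries that stood apart, and quantile normalization for Treg against Tconv, were chosen after seeing the data. The counts of called genes are given for CD28 deficiency in Nrp1+ Treg, Nrp1-negative Treg and Tconv, then for Nrp1+ against Nrp1-negative Treg in wild type and CD28-deficient mice. These were 25, 25, 97, 605 and 500. Leaving out each library in turn gave 12 to 34, 6 to 37, 44 to 258, 348 to 680 and 322 to 831. Blocked by replicate number they were 47, 41, 154, 1224 and 801, and every gene called without the block was called with it. Blocked within genotype the subsets differed in 1245 and 779 genes. Quantile normalization gave 51 and 80 in the Treg subsets and 1073 and 1139 between them. A pseudocount of 0.1 gave 3 and 11 in the Treg subsets and 368 between them in wild type. With no filter the count in Nrp1+ Treg was 68. With only the compared groups in the model it was 9 in Nrp1-negative Treg, 3 in Tconv, and 220 and 1212 between the subsets. Without the 3 libraries the counts were 130, 120, 311, 913 and 1853.

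Against Tconv the order is Nrp1+ Treg in wild type and CD28-deficient mice, then Nrp1-negative Treg in both. Quantile normalization gave 3098, 2815, 1259 and 1259, and leaving out the 3 libraries gave 2355, 2459, 1012 and 2082. Leaving out each library in turn gave 1140 to 2356, 1125 to 2124, 365 to 739 and 391 to 1392. For Nrp1-negative Treg the block gave 1129 and 1150, and within genotype 1047 and 1099.

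Between CD28 effects the order is Nrp1-negative against Nrp1+ Treg, Nrp1+ Treg against Tconv and Nrp1-negative Treg against Tconv (3, 15 and 9 genes). A pseudocount of 0.1 gave 1, 3 and 2, and leaving out the 3 libraries gave 5, 70 and 29. No filter gave 7 and 26 in the tests with Nrp1+ Treg. Only the compared groups gave 2 and 3 in the tests with Tconv. Nrp1+ Treg against Tconv gave 25 blocked within genotype and 3 to 36 with each library left out. Nrp1-negative Treg against Tconv gave 4 after quantile normalization and 4 to 25 with each library left out. Lists passing with the estimated correlation numbered 0, 4, 1, 0, 0, 0, 0, 5, 2, 1, 1 and 0 over the 12 comparisons in the order above. With the preset one they ranged over 6 to 12 between the Treg subsets' CD28 effects and 6 to 13 between those of Nrp1-negative Treg and Tconv. Pearson r of CD28 effects between the Treg subsets was 0.17 at a mean FPKM of 5 or more. With each library left out it ranged over 0.11 to 0.24 for the Treg subsets, 0.07 to 0.24 for Nrp1+ Treg and Tconv and 0.04 to 0.20 for Nrp1-negative Treg and Tconv.

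No named gene with a call in either fit turned its direction under the settings run, but the balance of higher and lower calls turned in several comparisons. Between the Treg subsets in CD28-deficient mice, 384 higher and 116 lower became 706 and 1147 without the 3 libraries and 603 and 609 with only the compared groups. Quantile normalization turned 1022 and 523 into 1426 and 1672 for Nrp1+ Treg against Tconv in wild type, and 1181 and 303 into 1399 and 1416 in CD28-deficient mice. For Nrp1-negative Treg against Tconv in wild type, 252 and 299 became 646 and 613 after quantile normalization and 761 and 251 without the 3 libraries. They became 295 and 282 without CD28-deficient Tconv replicate 3, and 507 and 232 without wild type Nrp1-negative Treg replicate 1. For CD28 deficiency in Tconv, 0 and 97 became 2 and 1 with only the compared groups. The oxidative phosphorylation and ribosomal lists in Tconv moved from below to above the other genes without the 3 libraries. Of the results for named genes with a library left out, 8672 stayed on their side of the threshold, 746 no longer passed and 14 newly passed. Under the other settings the numbers were 3269, 262 and 41. Settings with fewer libraries or groups have fewer degrees of freedom; otherwise the cause was not tested. Alternatives for raw counts were not run because the files hold FPKM, and the limit that depth sets on low genes is unknown.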

Other observations

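The lists and the tests of single genes in this part were planned, and the tests of explanations and the splits were chosen after the results were seen. The lists on metabolism, antigen receptor signalling, immediate early genes, Th17 genes, the cell cycle and heat shock had 0 called genes for CD28 deficiency, and also 0 when adjusted over the list alone unless stated. Medians are given for Nrp1+ Treg, Nrp1-negative Treg and Tconv, in that order. Glycolysis genes (18) had medians of -0.26, 0.06 and -0.35. The list passed in Nrp1+ Treg and Tconv with the preset correlation (adjusted p = 2.74e-06 and 0.00197), with an adjusted p = 0.436 and 0.576 with an estimated correlation. Oxidative phosphorylation genes (35) had medians of -0.21, 0.07 and -0.37 and cytosolic ribosomal protein genes (44) -0.21, 0.13 and -0.46. In Nrp1+ Treg these lists passed with the preset correlation (adjusted p = 4.49e-05 and 3.15e-05), with an adjusted p = 0.624 and 0.65 with an estimated correlation. In Tconv they passed as well (adjusted p = 5.01e-06 and 9.48e-10), with an adjusted p = 0.509 each with an estimated correlation. Without the 3 libraries that stood apart, camera placed both lists above the other genes in Tconv without passing (adjusted p = 0.885 and 0.353). Cholesterol synthesis genes (22) had medians of -0.12, 0.14 and -0.11, and antigen receptor and CD28 signalling components (28) -0.04, 0.21 and -0.26, with no pass.

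Immediate early genes (24) had medians of -0.30, -0.07 and -0.40. They passed with the preset correlation in both Treg subsets (adjusted p = 0.000107 and 3.37e-07), with an adjusted p = 0.436 and 0.189 with an estimated correlation. Th17 genes (7) had medians of 0.16, 0.45 and -0.37, with 2 higher in Nrp1-negative Treg when adjusted over the list alone. They passed in Nrp1+ Treg (adjusted p = 0.0202, and adjusted p = 0.436 with an estimated correlation). Cell cycle genes (29) had medians of -0.14 and -0.29 in Nrp1-negative Treg and Tconv, with 2 lower in Tconv when adjusted over the list alone. Their adjusted p was 1.19e-12 and 8.28e-05, with an adjusted p = 0.0917 and 0.509 with an estimated correlation. Heat shock genes (13) had medians of -0.03, 0.12 and -0.37 with no pass. Because camera compares a list with the other genes, its direction and the sign of the median differed for some lists without a pass, such as erythroid and platelet markers in Nrp1+ Treg and cholesterol synthesis in Nrp1-negative Treg.

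Of the 8 tested myeloid markers 0 were called, with medians of -0.02, 0.14 and -0.53, and of the 3 erythroid and platelet markers 0, with medians of -0.22, -0.09 and -0.33. Cd8b1 was 11.3 ± 1.20 in CD28-deficient and 8.46 ± 1.14 in wild type Tconv (0.38, adjusted p = 0.468), with Cd8a at 0.442 or less in each Tconv library. Xbp1, the 1 tested plasma cell gene, was 15.8 ± 1.52 against 20.1 ± 3.60 in Tconv (-0.32, adjusted p = 0.56). Cd1d1, the 1 tested gene of the NKT and gamma-delta list, was 17.9 ± 1.21 against 19.0 ± 1.71 (-0.08, adjusted p = 0.966). Of the 12 mitochondrially encoded genes 0 were in the files.

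Treg transcripts in CD28-deficient Tconv replicate 3 may come from Nrp1+ Treg cells, or RNA of them, mixed into the library: of 51 genes at least 8-fold higher in wild type Nrp1+ Treg than Tconv, 90.2% lay within 2-fold of the median share of 19.7% of the CD28-deficient Nrp1+ Treg level (quartiles 15.3% and 22.9%). Foxp3 stood at 21.5%, Nrp1 at 19.7% and Il2ra at 26.3%, and with no baseline taken off the median level of the 51 was 1.3%, 1.7% and 21.5% in replicates 1, 2 and 3. Exchange of cells or RNA both ways with CD28-deficient Nrp1+ Treg replicate 3 may account for both libraries: that library stood at a median of 21.6% of the Tconv level over 10 Tconv genes (quartiles 20.7% and 23.5%, 100% of genes within 2-fold), and with no baseline taken off at 28.3%, against 2.8% and 4.9% in replicates 1 and 2. Nrp1-negative Treg as the source are argued against by Nrp1, 16-fold above the highest CD28-deficient Nrp1-negative Treg library (0.798), and a whole Nrp1+ Treg library under a wrong label by Foxp3 at 24% of the lowest such library. The sort on the Foxp3 reporter would remove Treg cells, so a mixture after it and a failure of the sort stay open, as do Tconv that express Treg genes, which alone would not put Tconv transcripts into the Treg library.

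For the 12 genes lower in both Treg subsets, more myeloid cells in the wild type libraries are argued against. The 8 tested of 16 myeloid markers had a median of -0.02 (SD 0.18, median SE 0.31) in Nrp1+ Treg while the 12 genes changed by -0.88 to -1.66, and Cst3 was 47.9 ± 2.17 against 57 ± 4.46 and S100a8 11.7 ± 7.83 against 10.5 ± 1.33. Sequence of another strain around the disrupted Cd28 gene, acting on genes within that stretch, is argued against too. Of the 12 genes 10 had a position, 1 of them on the chromosome of Cd28, and 0 lay within 20 Mb of it. Whether such sequence acts on genes farther away was not tested. An effect of the genotype shared by all 3 populations is consistent with 11 of the 12 lying below the median change of all genes in CD28-deficient Tconv, where 78.1% of all tested genes were lower and 4 of the 12 were called. Strain sequence elsewhere in the genome stays open, since Cd22, Cebpa and Slc7a10, 3 of the 10, lie within 4.34 Mb on chromosome 7, and differences in housing or age were not tested.

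For the lower Th1 genes in CD28-deficient Tconv (median -1.66, 8 of 13 called), wild type Tconv replicate 1 alone is argued against as the whole source, since without it the median was -1.47 with 5 called. Without CD28-deficient replicate 3 the median was -1.82 with 9 called. NK cells in the wild type libraries, which a T cell sort would remove, cannot be told apart from a change in T cells. This is because the 5 tested of 10 NK markers (median -0.48) were low or are also made by T cells. Of the 5, 4 had a change below 0 and 1 above. Gzma was 3.03 ± 0.899 in wild type against 0.207 ± 0.155, Eomes 4.02 ± 1.7 against 1.47 ± 0.25 and Prf1 10.5 ± 0.452 against 7.36 ± 1.65. Klrb1c was 1.13 ± 0.268 against 0.535 ± 0.264, and Klrd1 14 ± 0.799 against 17.4 ± 8.67. Ncr1, too low to be tested, was 0.0757 or less. A smaller share of activated and memory cells among CD28-deficient Tconv is a candidate explanation that stays open, because the resting and naive list had an adjusted p = 0.687 with an estimated correlation and a median of -0.07. An effect of the genotype within each cell was not tested.

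For each of the 9 comparisons of 2 groups the 6 libraries make 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes as the real split. For CD28 deficiency the real counts of 25, 25 and 97 stood against 3, 2 and 1 in the highest other split. Between the Treg subsets 605 and 500 stood against 0 and 0, and against Tconv 1545, 1484, 551 and 718 stood against 1 each. Every other split mixes the 2 groups on each side, so a real difference adds to the spread and holds these counts down. The low counts therefore do not measure what chance gives. Where the numbers pair the libraries, 4 splits part all pairs, the real one included, and the other 6 keep 2 of the 3 pairs together. The highest other of the 4 gave 1 gene for CD28 deficiency in Tconv and for CD28-deficient Nrp1-negative Treg against Tconv, and 0 in the other 4 comparisons.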
